A study of Mus musculus with 5 samples.

How the data were processed

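Single-cell RNA sequencing was performed on 5 libraries of Msh2-knockout LKR13-H tumours from mice, 1 library per group. Per the labels' protocols, tumours were digested with collagenase IV and DNase, dead cells were excluded, and T cells, other immune cells and CD45-negative cells were sorted and combined at a ratio of 2:1:1 for each tumour before 10x Genomics 3′ library construction. The deposited values are whole-number UMI counts per gene and barcode, made with Cell Ranger, per the submitters' processing notes, which also name genome build mm10 and Seurat 4.0.3. The matrix header gives software version 3.1.0. The annotation release, and whether libraries were brought to equal depth when merged, are not given in the sources used here. The matrix holds 31053 genes and 33974400 barcodes, 6794880 per library, and is not restricted to cells.

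Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library against 2 simulated doublets per cell and removed at the expected rate of 0.8% per 1000 cells, which took 472, 534, 437, 819 and 712 barcodes from isotype, responding anti-PD-1, responding combination, resistant anti-PD-1 and resistant combination. Cells were clustered jointly without integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1; Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, leidenalg 0.10.2, igraph 0.11.9), and lymphocytes were clustered again on their own. A cluster was named from a marker list when at least 3 markers were detected and its leading genes did not go against the name, so every class name stands for cells that are like that type. Clusters 19 and 31 stayed unnamed. Lymphocyte clusters were parted by the share of cells with Ncr1 (at least 50%, NK), Foxp3 (at least 50%, regulatory T) and Cd8a or Cd8b1 (at least 70%, with Cd4 under 20%, CD8 T), and as conventional CD4 T where Cd4 was found at least 2 times as often as Cd8. These thresholds were set after the data were seen. Free RNA was measured in barcodes under 100 UMIs, and its share in a class was estimated from transcripts foreign to that class.

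Shares were computed within each sorted part, with exact Clopper-Pearson 95% intervals, and a share of 0 was given the limit allowed by 3 counts. Intervals cover counting error only, with no replicates behind them. For genes, UMIs were summed per library and class. Acquired resistance was compared with response in the 4 treated libraries with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using TMM normalization, filterByExpr, a model with treatment as an additive term and the quasi-likelihood test, with Benjamini-Hochberg adjustment at 0.05. This leaves 1 residual degree of freedom, the disagreement between the treatments, and edgeR moderates it with spread pooled over genes. The prior degrees of freedom were 222.2 in regulatory T cells and 4.95 to 12.22 in the other classes, so p-values in regulatory T cells rest almost wholly on pooled spread. The isotype library was not in the fit, and its values are given beside the others. The test was run in cancer, CD8 T, conventional CD4 T, regulatory T and macrophage and monocyte cells, each with at least 50 cells in every treated library. Neutrophils and NK cells also reached 50 cells, but were compared by list medians alone. Within each treatment the log2 ratio of CPM (pseudocount 1) was taken without a test. A list of genes with at least 5 CPM on average was set against 10000 random lists of the same size matched on mean expression in 20 bins. The hypoxia list was also counted per cancer cell after thinning to 2000 UMIs.

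The 32 gene lists, the design, the rule for naming genes and the alternative settings were fixed before the data were examined. Genes were named by that rule: in each class up to 4 members of each list with the largest absolute mean of the treatments' log2 ratios and at least 20 CPM in a treated library, the 10 higher and 10 lower genes of cancer cells and 5 higher and 5 lower of other classes by the smaller of the treatments' ratios, and Msh2 and Cd274 throughout. From the genes so named, 138 gene and class pairs were picked for the text, after their values were seen, and followed under every alternative. The 107 pairs whose call held throughout supplied most examples in the text, which therefore lean towards stable calls, and exceptions are given with their values. The alternatives were the DESeq2 1.42.0 Wald test in place of edgeR (on genes with at least 1 count), DESeq2 size factors, no filter on low counts, no treatment term, each treated library left out in turn (state alone in the model), minimum depths of 500 and 2000 UMIs, mitochondrial limits of 5% and 20%, doublets kept, free RNA subtracted, every cell thinned to 1000 UMIs, clustering resolutions of 0.5 and 2, pseudocounts of 0.1 and 5 CPM, list members at 20 CPM or with no minimum, TMM-scaled CPM, and the hypoxia list at 1000 UMIs, at 5000 UMIs and without thinning. Leaving out genes that share their 3′ end with another gene (5490 of 31053), and the DESeq2 test on the genes kept by filterByExpr, were added after the data were seen.

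Total UMIs ranged from 103589542 to 153788621 per library. The test was run on simulated counts with 50 genes changed at each of 4 known folds (48 of the 8-fold genes were tested in regulatory T cells); it recovered 12% (conventional CD4 T cells) to 52% (CD8 T cells) of 1.5-fold, 66% to 84% of 2-fold and 96% to 100.0% of 4-fold changes. False calls were 17 of 174 in cancer cells, 22 of 189 in CD8 T cells, 1 of 143 in conventional CD4 T cells, 4 of 153 in regulatory T cells and 29 of 188 in macrophages. Gene positions follow GRCm38, and 31011 of the 31053 genes had a position. Figures were drawn with matplotlib 3.10.9.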

Results

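Droplet-based 3′ single-cell RNA sequencing was applied to Msh2-knockout LKR13-H tumours grown in mice, where LKR13 is a lung adenocarcinoma line driven by mutant Kras and Msh2 encodes a DNA mismatch repair protein. The 5 libraries came from 5 groups, with 1 library each: isotype control antibody, response to anti-PD-1, response to anti-PD-1 + anti-CTLA-4, and acquired resistance to anti-PD-1 or to its combination with anti-CTLA-4. PD-1 and CTLA-4 are inhibitory receptors of T cells, and treatment began on day 10 after inoculation. The question, by the title of the series, was how hypoxia relates to acquired resistance. Total UMI counts were 103589542 in isotype, 115285168 and 126821024 in the responding libraries, and 153788621 and 151551432 in the resistant libraries, in the order anti-PD-1 and combination. The libraries gave 7358, 7728, 7062, 9421 and 8907 cells in the same order, with median depths of 4276, 4208, 5613.5, 5411 and 5751 UMIs per cell. The labels do not say how many tumours a library holds or whether libraries are independent, so p-values cannot speak beyond these libraries. They draw on the spread between these libraries and on spread pooled over genes. In regulatory T cells they rest almost wholly on the pooled spread. The fit rests on 4 treated libraries and 1 residual degree of freedom.

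Msh2 (ENSMUSG00000024151; chromosome 17, 87672330 to 87723713 in GRCm38) was counted at 5.55 CPM in cancer cells of the isotype library, 5.41 and 3.81 CPM in the responding libraries, and 5.80 and 5.98 CPM in the resistant libraries. Its 3′ tag may lie outside the deleted part, so these counts check nothing about the knockout. In cancer cells the log2 fold change of resistance over response was 0.40 (SE 0.178, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.111), and without the responding anti-PD-1 library it was 0.61 with an adjusted p of 0.00589. In CD8 T cells Msh2 rose by 0.42 (SE 0.110, edgeR adjusted p = 0.0208), a call lost without the responding combination library (0.0692), the resistant anti-PD-1 library (0.0686) or the resistant combination library (0.0939), and with DESeq2 (0.171), with log2 fold changes of 0.36 to 0.44 in those fits. With every cell thinned to 1000 UMIs it was 0.236 with an adjusted p of 0.319. In conventional CD4 T cells it rose by 0.82 (SE 0.214, edgeR adjusted p = 0.0188), a call lost without the resistant anti-PD-1 library (log2 fold change 0.831, adjusted p 0.149), without the resistant combination library (0.767, 0.161) and with every cell thinned to 1000 UMIs (1.093, 0.0584). Msh2 did not pass the test in regulatory T cells (log2 fold change -0.12, edgeR adjusted p = 0.777) or macrophages (0.03, 0.927).

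Regulatory T cells made up a larger share of T cells in the resistant libraries, and conventional CD4 T cells a smaller share. Regulatory T cells, which restrain other T cells, were 27.5% of T cells (Clopper-Pearson 95% interval 26.2 to 28.8, counting error only) in acquired resistance to anti-PD-1 against 7.61% (6.82 to 8.46) in response. Under the combination they were 17.6% (16.5 to 18.7) against 4.04% (3.44 to 4.72), and the isotype library held 13.4% (12.4 to 14.4). Conventional CD4 T cells were 8.77% (7.97 to 9.62) and 7.04% (6.33 to 7.82) in the resistant libraries, 17.3% (16.2 to 18.5) and 21.2% (19.9 to 22.5) in the responding libraries, and 19.9% (18.7 to 21.1) in isotype. CD8 T cells were 63.8% and 75.3% in resistance, 75.1% and 74.8% in response, and 66.7% in isotype. T cells, other immune cells and CD45-negative cells were sorted and mixed at a ratio of 2:1:1, so shares were read only within each part, and no test of shares between groups was run. At a coarser clustering resolution of 0.5 the conventional CD4 share was 11.1% in isotype and 11.5% in response to anti-PD-1.

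Fibroblasts and endothelial cells were nearly absent from the CD45-negative cells of the resistant libraries. Fibroblasts, the collagen-producing stromal cells, were 5.79% (4.82 to 6.89) and 22.8% (20.8 to 24.9) of CD45-negative cells in the responding libraries and 2.18% (1.54 to 2.99) in isotype. The resistant anti-PD-1 library held 0 of 3023 cells, which allows a share of up to 0.099%, and the resistant combination library held 1 of 2397 cells, or 0.042% (0.001 to 0.232). Endothelial cells numbered 20 and 23 in the responding libraries and 8 in isotype, against 0 in each resistant library. Among other immune cells, neutrophils were 18.7% (16.9 to 20.7) and 26.2% (24.1 to 28.4) in resistance, 13.5% (11.8 to 15.4) and 39.6% (37.1 to 42.1) in response and 7.03% (5.70 to 8.56) in isotype. NK cells were 9.06% (7.71 to 10.6) and 8.70% (7.40 to 10.1) in resistance, 21.5% (19.4 to 23.7) and 7.59% (6.32 to 9.02) in response, and 31.5% (28.9 to 34.1) in isotype. Macrophages and monocytes were 56.7% and 41.6% in resistance, 44.9% and 47.9% in response and 47.2% in isotype. Plasmacytoid dendritic cells, producers of type I interferon, were 3.64% (2.78 to 4.67) and 2.88% (2.14 to 3.79) in resistance, 1.24% (0.733 to 1.94) and 0.584% (0.267 to 1.10) in response, and 1.00% (0.536 to 1.71) in isotype. Neutrophils carried few UMIs (median 1185 to 1695 per library), and their share under a minimum of 2000 UMIs was 0.466% to 10.8%.

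**Figure D1:**
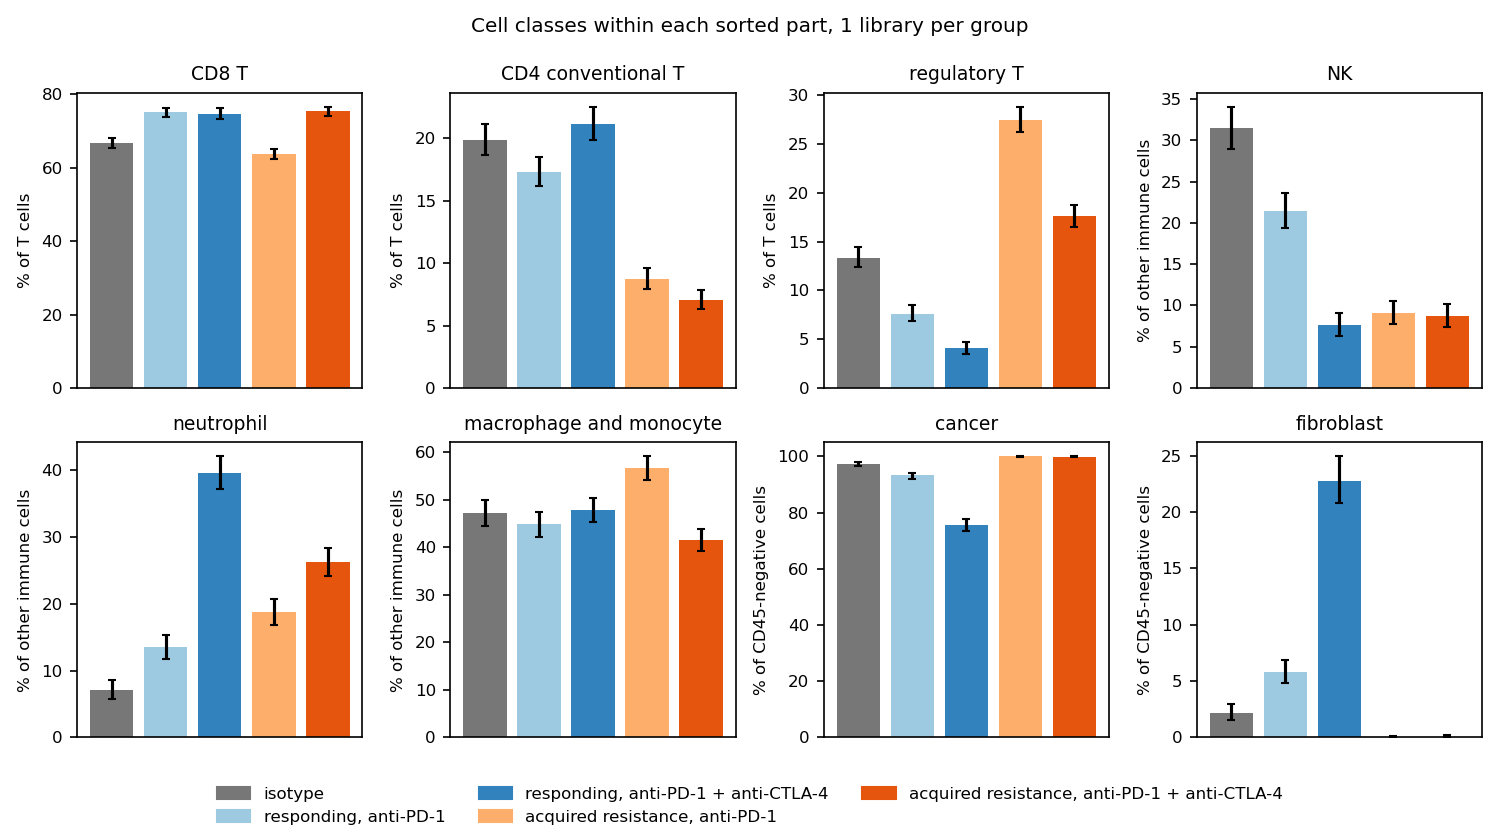
Share (%) of each cell class within its sorted part, 1 bar per library, with exact Clopper-Pearson 95% intervals that cover counting error only. Regulatory T cells stood at 27.5% and 17.6% in the resistant libraries against 7.61% and 4.04% in the responding libraries, and fibroblasts at 0 of 3023 and 1 of 2397 cells against 5.79% and 22.8%.

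Cancer cells of both resistant libraries had higher hypoxia and glycolysis transcripts than those of the responding libraries. Of 36 hypoxia genes tested, 26 rose and 2 fell (27 and 3 adjusted over the list alone), and of 17 glycolysis genes 13 rose and 1 fell (13 and 1 adjusted over the list alone). Car9 (chromosome 4, 43506966 to 43513729), a carbonic anhydrase induced by hypoxia-inducible factor, stood at 101 and 63.1 CPM in resistance, 24.0 and 13.3 CPM in response and 30.0 CPM in isotype, a log2 fold change of 2.19 (SE 0.110, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 6.83e-06). Adm, which encodes the vasodilator peptide adrenomedullin, rose by 2.36 (SE 0.128, edgeR adjusted p = 1.12e-05), and Hilpda, a lipid droplet protein, by 1.58 (SE 0.119, edgeR adjusted p = 4.4e-05). Vegfa, the vascular growth factor, rose by 0.86 (SE 0.107, edgeR adjusted p = 0.000566). Among glycolytic enzymes, Pgk1 (X chromosome, 106187100 to 106203699) was at 2617 and 2210 CPM in resistance, 1128 and 1042 CPM in response and 1212 CPM in isotype, a log2 fold change of 1.18 (SE 0.157, edgeR adjusted p = 0.000771), while Aldoc rose by 2.46 and Gpi1 by 1.29. Hexokinase 2 (Hk2), the first enzyme of the pathway and a member of both lists, fell by 1.36 on the log2 scale (SE 0.133, edgeR adjusted p = 0.000181). The median log2 ratio of the hypoxia list was 0.62 under anti-PD-1 and 0.94 under the combination, and that of glycolysis 0.83 and 0.72, each at percentile 100.0 among 10000 random lists matched on mean expression. Several list members, such as Bnip3 (75.9% of its 3′ end shared with another gene), Gapdh (63.2%) and Eno1 (89.7%), could not be counted apart from near-identical copies.

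Interferon-responsive and antigen presentation genes were lower in cancer cells of both resistant libraries. All 8 MHC class II genes tested fell (8 adjusted over the list alone), as did 22 of 25 interferon-γ response genes (22), 20 of 23 type I interferon response genes (20) and 15 of 18 MHC class I presentation genes (16 adjusted over the list alone), and none of the members tested rose. Cxcl9 (ENSMUSG00000029417; chromosome 5, 92321347 to 92328079), a chemokine that attracts T cells, was at 23.01 and 24.55 CPM in resistance, 389 and 649 CPM in response and 198 CPM in isotype, and fell by 4.37 on the log2 scale (SE 0.199, edgeR adjusted p = 4.59e-06). Iigp1, an interferon-inducible GTPase, fell by 3.39 (SE 0.271, edgeR adjusted p = 6.06e-05). The peptide transporter Tap1 (chromosome 17, 34187553 to 34197225) fell by 2.11 (SE 0.183, edgeR adjusted p = 9.52e-05) and the immunoproteasome subunit Psmb8 by 1.79 (SE 0.218, edgeR adjusted p = 0.000502). H2-Ab1, an MHC class II chain, fell by 3.01 (SE 0.251, edgeR adjusted p = 8.04e-05) and its transactivator Ciita by 3.29 (SE 0.191, edgeR adjusted p = 1.39e-05). Of 17 immune checkpoint ligand genes 7 fell and none rose (8 fell adjusted over the list alone). Cd274 (chromosome 19, 29367455 to 29388095), which encodes PD-L1, was at 4.31 and 3.31 CPM in resistance, 14.7 and 30.6 CPM in response and 9.93 CPM in isotype, and fell by 2.45 (SE 0.300, edgeR adjusted p = 0.000514). The list medians were -2.09 and -3.03 for interferon-γ response, -0.98 and -1.32 for MHC class I and -2.28 and -3.38 for MHC class II, all at percentile 0.0 among 10000 random lists matched on mean expression. For type I interferon response they were -0.94 and -1.28, also at percentile 0.0. Of 20 immune cell transcripts foreign to cancer cells 9 fell and 3 rose (11 and 4 adjusted over the list alone), with medians of -0.235 at percentile 26.1 and -0.509 at percentile 0.35. With free RNA subtracted the medians of the interferon-γ, type I interferon, MHC class I and MHC class II lists stayed at percentile 0.0.

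Proliferation and NF-κB response genes were also lower in resistant cancer cells, and cholesterol synthesis genes higher. Of 30 proliferation genes 28 fell and none rose (29 adjusted over the list alone), among them Mki67, a marker of cycling cells, by 1.30 (SE 0.114, edgeR adjusted p = 9.72e-05). The list medians were -0.60 and -0.64, at percentile 0.0 among 10000 random lists matched on mean expression. The cycling cells of cluster 8 were 13.4% and 15.7% of cancer cells in resistance, 28.6% and 35.9% in response and 22.7% in isotype, and within that cluster the medians were -0.003 and 0.16. Of 18 TNF and NF-κB response genes 14 fell and 1 rose (14 and 1 adjusted over the list alone), with medians of -0.62 and -0.90 at percentiles 0.01 and 0.0. DESeq2 on genes with at least 1 count called 10 of 20 of these genes and 23 of 30 proliferation genes lower. The chemokine Ccl2 fell by 3.43 (SE 0.422, edgeR adjusted p = 0.000523) and Lcn2, an iron-binding secreted protein, by 4.38 (SE 0.187, edgeR adjusted p = 3.49e-06). Of 18 cholesterol synthesis genes 14 rose and none fell (14 adjusted over the list alone), with medians of 0.37 and 1.09 at percentile 100.0. This rise was not particular to cancer cells: the list medians were positive in every class compared, at 0.659 and 1.565 in CD8 T cells. Under anti-PD-1 those of macrophages (0.12) and neutrophils (0.028) lay inside the range of random lists. Insig1, a regulator of sterol synthesis, rose by 1.45 (SE 0.192, edgeR adjusted p = 0.000749). Of 11 gastric lineage genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), and of 12 epithelial genes 7 rose and none fell (7 adjusted over the list alone), including the keratin Krt7 (1.03, SE 0.124, edgeR adjusted p = 0.000483). Within cluster 8 the epithelial medians of 0.258 and 0.233 lay inside the range of random lists. Of 18 mesenchymal genes 1 rose and 11 fell (1 and 11 adjusted over the list alone), but DESeq2 on genes with at least 1 count called 6 of 21 lower, the medians of -0.212 and -0.052 within cluster 8 lay inside the range of random lists, and fibroblast markers in barcodes under 100 UMIs were also lower in resistance (273 and 370.5 CPM against 1300.3 and 3110.5 CPM in response). Genes of oxidative phosphorylation split 4 higher and 9 lower of 35 (4 and 9 adjusted over the list alone). The medians of mitochondrial genes were -0.127 and 0.368, at percentiles 24.0 and 99.7. Those of dissociation stress genes were -0.025 and -0.28, at percentiles 53.8 and 2.03.

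In all, 4592 of 13891 genes tested in cancer cells passed at an adjusted p of 0.05 by edgeR, 2115 higher and 2477 lower in resistance. The count was 2894 by the DESeq2 Wald test on the same genes, 951 without the resistant anti-PD-1 library and 1065 without the resistant combination library, and every cell thinned to 1000 UMIs gave 1852. Cancer cells of the states lay largely in different clusters: cluster 5 held 49.1% and 59.7% of them in response and 6.2% and 3.5% in resistance, whereas cluster 6 held 33.4% and 40.2% in resistance and 12.4% and 0.7% in response. Cluster 5 was led by Iigp1 and Cxcl9, cluster 7 by Hilpda. A set of transcripts, chosen after their values were seen, shifted with state in all 5 classes tested, isotype included on the side of response. In cancer cells Gm42418 was at 622 and 605 CPM in resistance, 4866 and 3824 CPM in response and 5707 CPM in isotype, and Uba52, whose 3′ end is shared in full with other genes, was at 720.1 and 811 CPM against 147, 179 and 143 CPM. Library preparation and state cannot be told apart in this design. Free RNA made up 1.96% and 1.64% of cancer-cell UMIs in resistance, 1.83% and 2.01% in response and 1.55% in isotype.

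**Figure D2:**
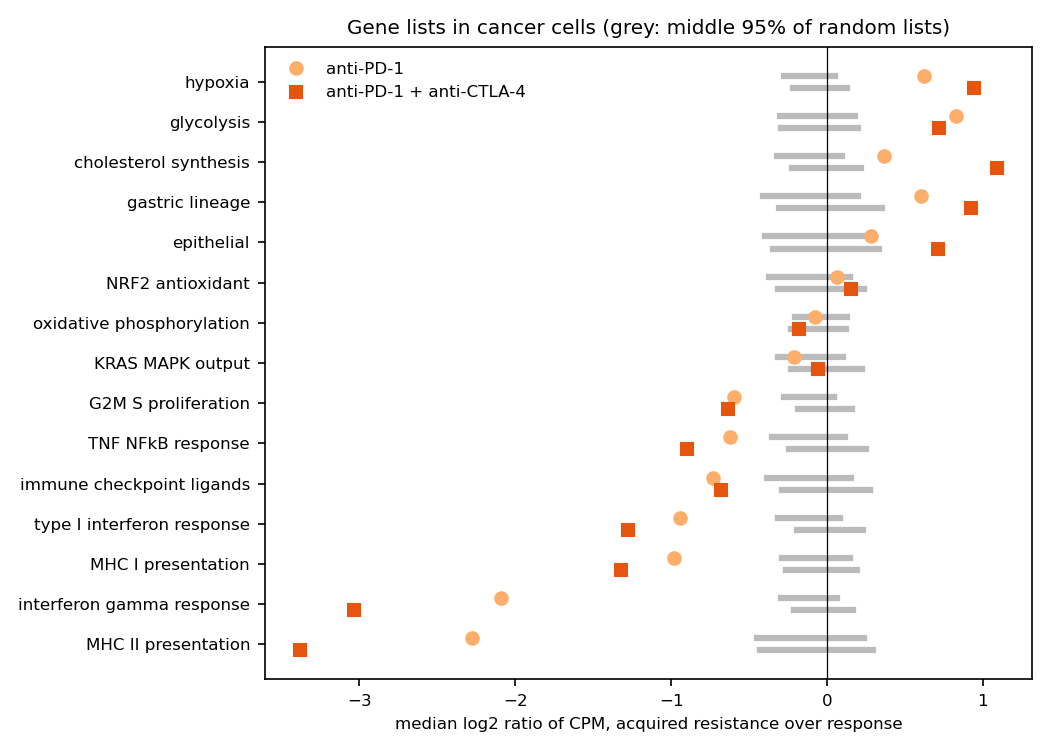
Median log2 ratio of CPM, resistance over response, for 15 gene lists in cancer cells, with circles for anti-PD-1 and squares for the combination. Grey bars span the middle 95% of 10000 random lists matched on mean expression, and the interferon-γ list lies at -2.09 and -3.03.

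**Figure D3:**
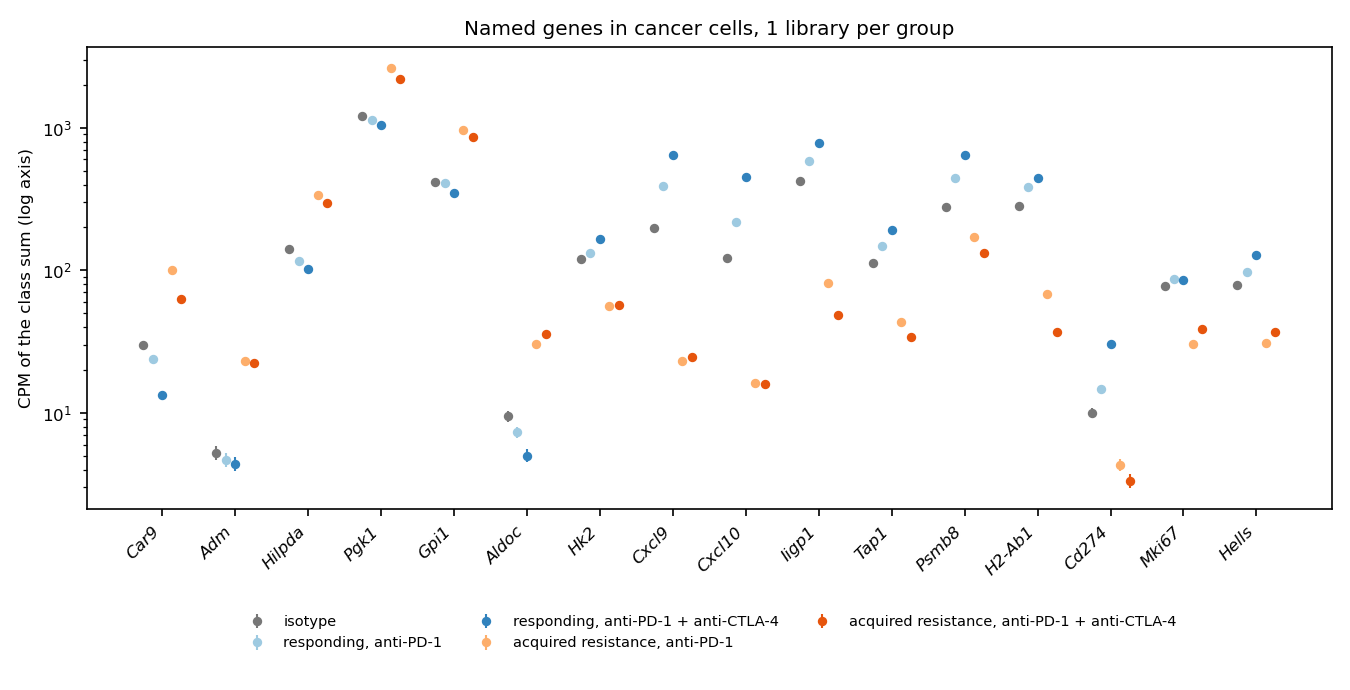
CPM of the cancer-cell sum (log axis) for named genes, 1 point per library, with 95% Poisson intervals that cover counting error only. Car9 lay at 101 and 63.1 CPM in the resistant libraries against 24.0 and 13.3 CPM in the responding libraries.

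The share of hypoxia-list UMIs was also examined per cancer cell, at a fixed depth of 2000 UMIs. The median cell carried 0.40% (95% interval 0.35 to 0.40) and 0.35% (0.30 to 0.35) in the resistant libraries, 0.20% (0.20 to 0.25) and 0.20% (0.20 to 0.20) in the responding libraries and 0.25% in isotype. At the top decile the share was 1.10% (1.05 to 1.15) and 1.05% (1.00 to 1.10) in resistance, 0.70% (0.65 to 0.75) and 0.57% (0.55 to 0.60) in response, and 0.80% (0.70 to 0.85) in isotype. These values came from 2972, 2383, 1880, 1197 and 1636 cells in that order, and cells are not replicates. At 2000 UMIs a share moves in steps of whole UMIs, so medians and their intervals fall on few values. The interval of 0.20 to 0.20 reflects these steps rather than precision. Without thinning the medians were 0.396% and 0.322% in resistance, 0.215% and 0.197% in response and 0.239% in isotype. The unthinned top decile was 1.03% and 0.99% in resistance, 0.635% and 0.533% in response.

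**Figure D4:**
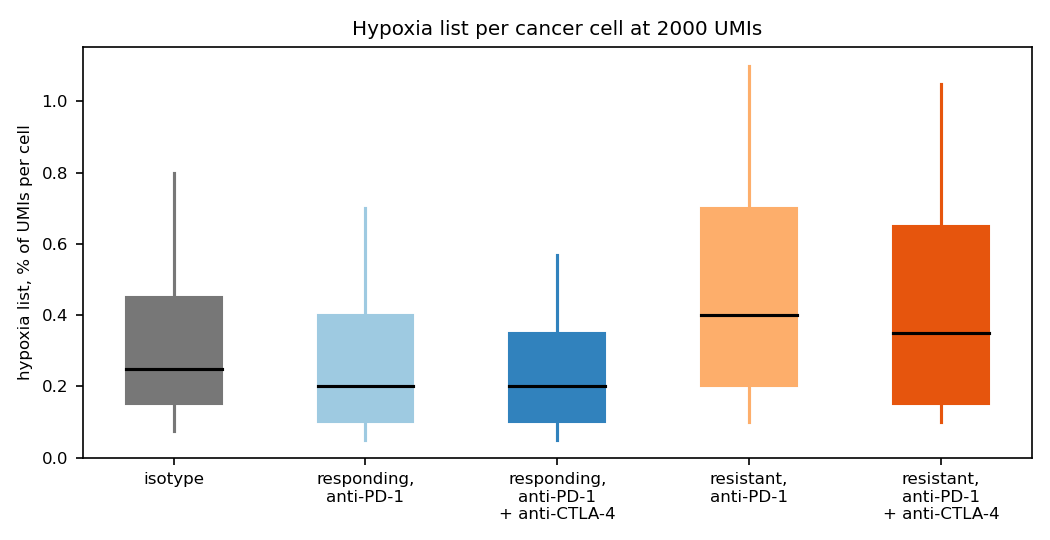
Hypoxia-list UMIs as a percentage of all UMIs per cancer cell, after thinning to 2000 UMIs: the line is the median, the box the 25th to 75th and the whisker the 10th to 90th percentile of cells, for each library. The medians were 0.40% and 0.35% in resistance and 0.20% in both responding libraries.

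CD8 T cells of the resistant libraries had lower exhaustion, cytotoxic and tissue residency transcripts and higher naive and memory, type I interferon and proliferation transcripts. Of 20 exhaustion genes 13 fell and none rose (13 adjusted over the list alone), of 23 cytotoxic effector genes 11 fell and 1 rose (11 and 1), and of 10 residency genes 7 fell (7 adjusted over the list alone). DESeq2 on genes with at least 1 count called 11 of 22 exhaustion, 7 of 23 cytotoxic effector and 7 of 10 residency genes lower. Gzma (chromosome 13, 113093825 to 113100981), a granule protease of killer cells, was at 378 and 62.0 CPM in resistance, 2519.7 and 1334 CPM in response and 1296 CPM in isotype, and fell by 3.45 (SE 0.363, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 0.000957). That call was lost without the responding anti-PD-1 library (log2 fold change -2.501, adjusted p = 0.0912). Havcr2, which encodes the inhibitory receptor TIM-3, fell by 2.59 (SE 0.331, edgeR adjusted p = 0.00179), and Nr4a3, a transcription factor induced by T cell receptor signalling, by 2.92 (SE 0.239, edgeR adjusted p = 0.000484). Of 17 naive and memory genes 10 rose and 2 fell (10 and 3 adjusted over the list alone). Bcl2, which protects cells from death, rose by 2.49 (SE 0.309, edgeR adjusted p = 0.00165), and Ccr7, a lymph node homing receptor, by 2.17 (SE 0.111, edgeR adjusted p = 0.000142). The medians were -0.51 and -0.72 for exhaustion, -0.45 and -1.32 for cytotoxic effectors, -0.63 and -0.76 for residency and 0.46 and 1.08 for naive and memory genes, at percentiles 0.24 or lower and 100.0 among 10000 random lists matched on mean expression. When only members at 20 CPM or more were used, the naive and memory median under anti-PD-1 was 0.085 at percentile 85.1, and with every cell thinned to 1000 UMIs the T cell exhaustion median of that treatment was -0.395 at percentile 2.81.

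Type I interferon, cholesterol synthesis, glycolysis and proliferation lists were higher in CD8 T cells of the resistant libraries. Of 23 type I interferon genes 18 rose and 1 fell (18 and 1 adjusted over the list alone), with medians of 0.68 and 1.88 at percentile 100.0 among 10000 random lists matched on mean expression. Rtp4, an interferon-induced gene, rose by 2.03 (SE 0.13, edgeR adjusted p = 0.000258). Of 18 cholesterol synthesis genes 16 rose (17 adjusted over the list alone), including Fdps, which makes farnesyl diphosphate (2.5, SE 0.376, edgeR adjusted p = 0.00301). Of 30 proliferation genes 25 rose and none fell (26 and 1 adjusted over the list alone), including Rrm2, a subunit of ribonucleotide reductase (1.18, SE 0.090, edgeR adjusted p = 0.000437). Of 17 glycolysis genes 14 rose and 1 fell (14 and 1 adjusted over the list alone), and of 18 MHC class I genes 12 rose and 1 fell (14 and 1 adjusted over the list alone). Hypoxia genes split 11 higher and 5 lower of 34 (11 and 5 adjusted over the list alone). Their medians were 0.124 in both treatments, at percentiles 98.4 and 98.0, above the range of random lists. Oxidative phosphorylation genes split 15 higher and 6 lower of 35 (17 and 7 adjusted over the list alone), with medians of 0.121 and 0.019 inside that range. Of 21 dissociation stress genes 12 fell and 6 rose (12 and 6 adjusted over the list alone), with medians of -0.59 and -1.07 at percentile 0.0, and Egr1, an immediate early gene, fell by 2.01 (SE 0.311, edgeR adjusted p = 0.00325). DESeq2 on genes with at least 1 count called 12 of 23 type I interferon, 12 of 18 cholesterol synthesis, 20 of 30 proliferation and 13 of 18 glycolysis genes higher. Lists of other cell types were lower in this class too: the medians were -1.39 and -1.27 for transcripts of cancer cells, -1.39 and -1.5 for mesenchymal genes, -0.91 and -1.6 for inflammatory macrophage genes and -1.73 and -2.0 for MHC class II genes. Of 11 mitochondrial genes 6 rose and 2 fell (6 and 2 adjusted over the list alone). By edgeR 4548 of 11683 genes passed, 2219 higher and 2329 lower, against 2120 by DESeq2 on the same genes, 2768 without the responding anti-PD-1 library, 2457 without the resistant anti-PD-1 library and 2011 without the resistant combination library. CD8 T cells lay mainly in lymphocyte clusters 0, 1 and 3 in response and in clusters 2 and 6 in resistance. Cycling CD8 T cells differed in cluster too: cluster 11 held 1.5% and 0.5% in resistance and 5.1% and 7.2% in response, cluster 13 4.2% and 9.3% against 0.1% in each, cluster 15 4.7% and 7.7% against 0.0%, and cluster 20 1.4% and 2.0% against 0.8% and 1.7%. Cluster 2 held 43.2% and 31.8% of them in resistance and 0.5% and 0.1% in response. Gm42418 was at 898 and 866 CPM in resistance against 16955 and 15218 CPM, and free RNA was 1.73% and 1.42% of CD8 T cell UMIs against 4.49% and 3.46%.

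Conventional CD4 T cells of the resistant libraries had higher granzyme C and naive or memory transcripts and lower Ccr2. Gzmc (chromosome 14, 56231441 to 56234656), a granule protease, was at 618 and 655 CPM in resistance, 13.0 and 21.4 CPM in response and 47.1 CPM in isotype, and rose by 5.20 (SE 0.175, edgeR adjusted p = 7.39e-10). Ecm1, a secreted matrix protein, rose by 3.94 (SE 0.137, edgeR adjusted p = 7.42e-10), the co-stimulatory receptor Tnfrsf9 by 2.45 (SE 0.144, edgeR adjusted p = 2.12e-07) and Ccr7 by 2.56 (SE 0.158, edgeR adjusted p = 3.31e-07). The chemokine receptor Ccr2 fell by 2.11 (SE 0.145, edgeR adjusted p = 9.36e-07). Of 17 naive and memory genes 8 rose and 1 fell (11 and 2 adjusted over the list alone), with medians of 0.80 and 0.77 at percentile 100.0 among 10000 random lists matched on mean expression, but 0.247, inside the range of random lists, under anti-PD-1 in cells with at least 2000 UMIs. Of 18 cholesterol synthesis genes 12 rose (12 adjusted over the list alone) and of 16 glycolysis genes 12 rose (12 and 1 lower adjusted over the list alone). DESeq2 on genes with at least 1 count called fewer: 2 of 18 cholesterol synthesis genes higher (5 adjusted over the list alone), 8 of 18 glycolysis genes (9) and 4 of 18 naive and memory genes (8). Fdps rose by 2.16 (SE 0.238, edgeR adjusted p = 6.84e-05), a call lost without the resistant combination library (log2 fold change 1.862, adjusted p 0.0539), and Pfkl, a glycolytic enzyme, by 1.20 (SE 0.142, edgeR adjusted p = 0.000114), lost without the resistant anti-PD-1 library (1.14, 0.0561). Of 21 cytotoxic effector genes 4 rose and 8 fell (4 and 8 adjusted over the list alone). Of 20 dissociation stress genes 1 rose and 10 fell (1 and 10 adjusted over the list alone), and of 11 mitochondrial genes 7 rose and none fell (7 and 1 adjusted over the list alone). Lists of other cell types were lower too, with medians of -1.209 and -0.954 for transcripts of cancer cells (percentiles 0.12 and 0.14), -1.094 and -0.375 for mesenchymal genes (0.0 and 1.81) and -1.001 and -0.442 for MHC class II genes (0.02 and 3.74). By edgeR 1583 of 8768 genes passed, 715 higher and 868 lower, but 52 without the resistant anti-PD-1 library and 69 without the resistant combination library, 274 by DESeq2 on the same genes and 631 with every cell thinned to 1000 UMIs. The class lay mainly in lymphocyte clusters 5 and 9 in response and in cluster 14 in resistance (57.7% and 59.3% against 0.8% and 0.2%). Free RNA was 2.36% and 1.42% of UMIs in resistance against 5.64% and 4.24% in response, and Gm42418 was at 1066 and 962 CPM against 18012 and 15836 CPM.

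Regulatory T cells of the resistant libraries had higher hypoxia, glycolysis and cholesterol synthesis transcripts and lower interferon-γ response and naive or memory transcripts. Of 30 hypoxia genes 17 rose and 1 fell (20 and 1 adjusted over the list alone), of 18 glycolysis genes 13 rose (16 adjusted over the list alone) and of 18 cholesterol synthesis genes 15 rose (17 adjusted over the list alone). DESeq2 on genes with at least 1 count called 11 of 38 hypoxia genes higher (14 adjusted over the list alone), 12 of 18 glycolysis genes (13), but 3 of 18 cholesterol synthesis genes (9). The edgeR p-values of this class rest almost wholly on spread pooled over genes, with prior degrees of freedom of 222.2. Laptm4b (chromosome 15, 34238028 to 34284302), a lysosomal membrane protein, was at 175 CPM in both resistant libraries, 16.7 and 14.7 CPM in response and 24.8 CPM in isotype, and rose by 3.47 (SE 0.215, edgeR adjusted p = 3.06e-36). Ero1l, an oxidase of protein folding in the endoplasmic reticulum, rose by 1.70 (SE 0.170, edgeR adjusted p = 2.63e-17), the glucose transporter Slc2a1 by 1.32 (SE 0.174, edgeR adjusted p = 8.41e-11) and Pdcd1, which encodes PD-1, by 1.20 (SE 0.195, edgeR adjusted p = 1.48e-07). Of 24 interferon-γ response genes 13 fell and 2 rose (13 and 2 adjusted over the list alone) and of 17 naive and memory genes 10 fell (11 adjusted over the list alone). By DESeq2 5 of 25 interferon-γ response genes were lower and 2 higher (8 and 2 adjusted over the list alone), and 5 of 18 naive and memory genes were lower (6). Of 6 transcripts of cancer cells 4 fell (4 adjusted over the list alone), with medians of -1.163 and -0.371 at percentiles 0.0 and 4.69, and of 12 mesenchymal genes 6 fell and 2 rose (6 and 2), with medians of -0.422 and -0.737 at percentiles 1.83 and 0.01. The guanylate-binding protein Gbp2 fell by 1.10 (SE 0.163, edgeR adjusted p = 8.7e-09) and S1pr1, a receptor for exit from tissue, by 1.5 (SE 0.201, edgeR adjusted p = 1.57e-10). The medians were 0.71 and 0.73 for hypoxia, 0.99 and 0.77 for glycolysis, and -0.49 and -0.39 for interferon-γ response, at percentiles 100.0, 100.0 and 0.01 or lower among 10000 random lists matched on mean expression. By edgeR 2014 of 9598 genes passed, 937 higher and 1077 lower, against 312 by DESeq2 on the same genes, 423 with thinned cells, 510 without a filter on low counts, 757 without the resistant anti-PD-1 library and 952 without the resistant combination library. Lymphocyte cluster 4 held 89.7% and 84.7% of the class in resistance and cluster 7 held 87.9% and 81.7% in response. Free RNA was 2.62% and 2.5% of UMIs against 5.42% and 3.88%, and Gm42418 was at 889 and 831 CPM against 15620 and 13035 CPM.

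Macrophages and monocytes of the resistant libraries had higher hypoxia, glycolysis and type I interferon transcripts and lower interferon-γ response and MHC class II transcripts. Spp1 (chromosome 5, 104435118 to 104441050), which encodes osteopontin, was at 5115 and 4075 CPM in resistance, 635 and 375 CPM in response and 530 CPM in isotype, and rose by 3.30 (SE 0.137, edgeR adjusted p = 0.000597). Of 34 hypoxia genes 19 rose and 1 fell (23 and 1 adjusted over the list alone), including Egln3, an oxygen-sensing prolyl hydroxylase (1.99, SE 0.13, edgeR adjusted p = 0.0015), and Hilpda (1.83, SE 0.136, edgeR adjusted p = 0.00229). Of 17 glycolysis genes 12 rose and 1 fell (14 and 1 adjusted over the list alone). Of 23 type I interferon genes 21 rose (23 adjusted over the list alone), including the antiviral gene Rsad2 (2.76, SE 0.115, edgeR adjusted p = 0.000597). Of 24 interferon-γ response genes 17 fell (19 adjusted over the list alone), with Cxcl9 at 34.3 and 117 CPM in resistance, 1070 and 500 CPM in response and 886 CPM in isotype (-3.40, SE 0.652, edgeR adjusted p = 0.021). Of 8 MHC class II genes 6 fell (7 adjusted over the list alone), including H2-Ab1 (-0.95, SE 0.111, edgeR adjusted p = 0.00622). DESeq2 on genes with at least 1 count called 15 of 38 hypoxia, 11 of 18 glycolysis and 16 of 23 type I interferon genes higher, and 11 of 25 interferon-γ response and 5 of 8 MHC class II genes lower. Of 30 proliferation genes 14 rose and none fell (19 adjusted over the list alone), with medians of 0.56 and 1.02, but -0.39 under anti-PD-1 with every cell thinned to 1000 UMIs. Lists of other cell types were lower too, with medians of -1.16 and -1.06 for transcripts of cancer cells and -1.125 and -0.708 for mesenchymal genes, at percentiles 0.01 or lower. Dissociation stress genes stood at -0.072 and -0.446, at percentiles 33.7 and 0.03. The chemokine Ccl8 fell by 2.02 (SE 0.115, edgeR adjusted p = 0.00114). The medians were 0.71 and 0.74 for hypoxia, 1.04 and 1.51 for type I interferon, -1.06 and -0.60 for interferon-γ response and -1.01 and -0.56 for MHC class II, beyond all but 0.17% of 10000 random lists matched on mean expression. By edgeR 2256 of 11177 genes passed, 1064 higher and 1192 lower, against 829 by DESeq2 on the same genes, 3580 without a filter on low counts and 726 with thinned cells. Cluster 16 held 59.5% and 48.5% of the class in resistance and cluster 11 held 76.8% and 75.9% in response. Free RNA was 2.5% and 2.22% of UMIs against 6.02% and 5.22%, and Gm42418 was at 1164 and 1216 CPM against 13408 and 13147 CPM.

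**Figure D5:**
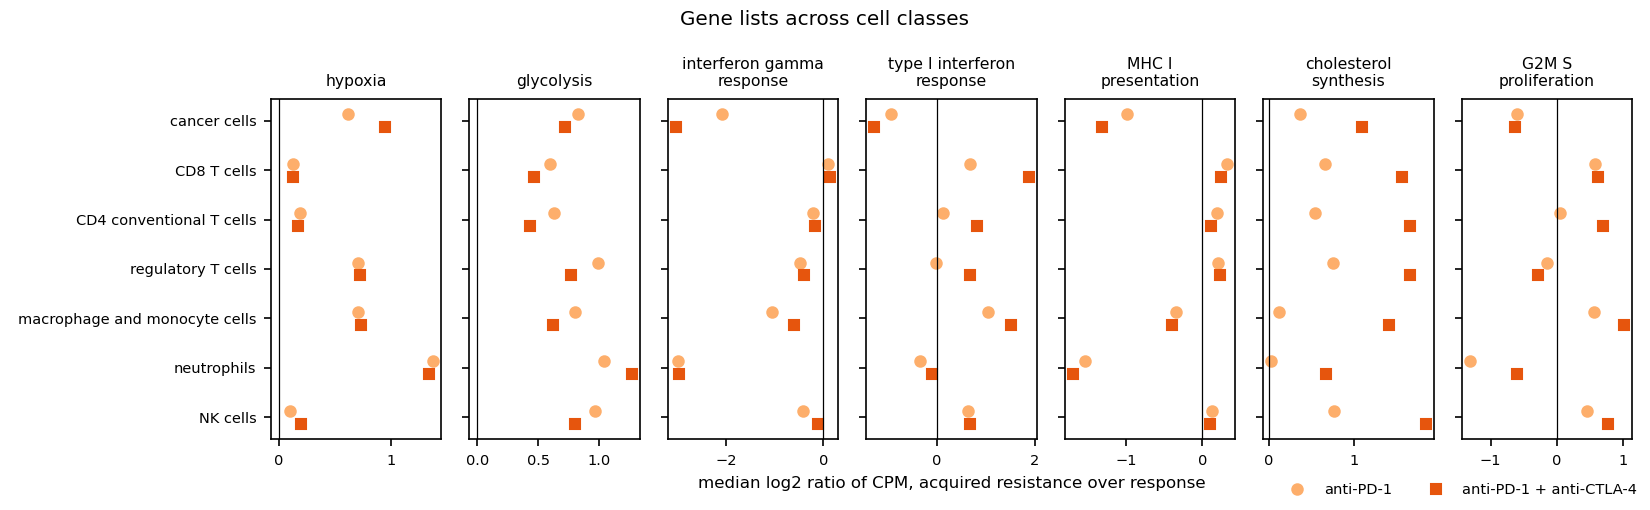
Median log2 ratio of CPM, resistance over response, for 7 gene lists in 7 cell classes, with circles for anti-PD-1 and squares for the combination. The interferon-γ list lay at -2.09 and -3.03 in cancer cells and 0.09 and 0.14 in CD8 T cells.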

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

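Of the tests in this part, those of transcript length and of the mix of cancer-cell clusters were written before their results were seen, and those of shared 3′ ends, library factors, partings of the libraries, free RNA subtraction and fibroblast markers were chosen after.

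NK cells drew attention because the ratio of resistance over response for MHC class II transcripts differed in sign between the treatments. The median log2 ratio over 8 members was -0.698 under anti-PD-1 and 0.593 under the combination, and the difference was not tested. With free RNA subtracted the anti-PD-1 median was 0.513, and with every cell thinned to 1000 UMIs the combination median was -0.087, so neither sign held under both. An unnamed group of cells, cluster 31, made up 0.265% of cells (25 of 9421) in the resistant anti-PD-1 library, above the isotype library with 0.0408% (upper 95% limit 0.119%). The resistant combination library held 0.101% (0.0462 to 0.192), an interval that overlaps that of isotype. In the responding libraries it was 0 of 7728 cells under anti-PD-1 and 0.0566% under the combination. Its leading genes mixed neutrophil transcripts such as Retnlg and Cxcl2 with the T cell transcripts Gzmf and Cd8b1, and no explanation was tested.

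Hypoxia and glycolysis transcripts were higher in cancer cells of both resistant libraries. Without genes sharing 3′ ends, 27 of 30 hypoxia and 14 of 16 glycolysis members remained, and all 4 list medians stayed above the middle 95% of random lists. Most members were higher and few were left out, so the medians could hardly fall to the bound. This shows only that the rise did not rest on the members left out. All 4 medians also stayed above that range against lists matched on transcript length, which argues against length. The 1 nearest to its bound, glycolysis under the combination, was 0.742 (bound 0.213) without shared 3′ ends and 0.719 (bound 0.212) against lists matched on length. A factor of library preparation acting alike in every class would move CD8 T cells as much, and no other class was compared in this way. The cancer-cell excess over CD8 T cells was 0.364 (bound 0.116) for hypoxia, under the treatment nearer its bound. This argues against a factor acting on CD8 T cells as much as on cancer cells as the whole cause of the hypoxia shift. The hypoxia list was higher in the other classes too. Its anti-PD-1 medians were 0.621 in cancer cells, 0.124 in CD8 T, 0.188 in conventional CD4 T and 0.71 in regulatory T cells. They were 0.71 in macrophages, 1.38 in neutrophils and 0.104 in NK cells, the last inside the range of random lists. The rise was thus not particular to cancer cells, and a factor shared by some classes stays open. For glycolysis the excess was 0.331 (bound 0.133) under anti-PD-1 and 0.165 (bound 0.225) under the combination. The glycolysis list was higher in all 7 classes. Its anti-PD-1 medians were 0.826 in cancer cells, 0.597 in CD8 T, 0.632 in conventional CD4 T and 0.988 in regulatory T cells. They were 0.803 in macrophages, 1.04 in neutrophils and 0.962 in NK cells, so a factor shared by the classes stays open for glycolysis. A batch that coincides with state cannot be told apart from it, since 737 of 3701 genes lay on the same side in every class when the libraries were parted by state, against at most 118 for the other 9 of the 10 partings. Oxygen supply in the tumours stays open as the biological explanation and was not tested.

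Interferon-γ response and MHC class I transcripts were lower in resistant cancer cells. Of the 4 medians, the 1 nearest to its bound, MHC class I under anti-PD-1, was -1.075 after free RNA was subtracted (bound -0.299), -1.104 within cluster 8 (bound -0.227) and -1.181 as the cancer-cell difference from CD8 T cells (bound -0.258). The value after subtraction argues against immune RNA in cancer-cell barcodes as the whole cause. The difference from CD8 T cells argues against a preparation factor shared with that class as the whole cause. The value within cluster 8 shows only that the lists were lower there too. Cluster 8 was led by cell-cycle genes such as Birc5 and Cdc20, so it may itself hold a changed mix of cells. A shift in the mix of cancer cells therefore stays open. A batch that coincides with state cannot be told apart from it in this design. Lower interferon-γ signalling in resistance was not tested by itself.

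Fibroblasts and endothelial cells were nearly absent from the resistant libraries. If fibroblasts had been lost at the cell filters, their markers would remain over every barcode with at least 500 UMIs and no other filter, but the higher upper 95% limit of the ratio of resistance to response was 0.00997 there, against a bound of 0.5. If they had been named as another class, their markers would remain over all cells, where the same limit was 0.00447. In barcodes under 100 UMIs the resistant libraries held 273 and 370.5 CPM of fibroblast markers against 738 CPM in isotype, while over all cells they held 4.8 and 5.6 CPM against 387 CPM, so fibroblast RNA was scarcer in their cells than in their free RNA. Different recovery in digestion or sorting, and a true loss from the tumours, both stay open and were not tested.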

How the results depend on the processing

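The alternatives without genes that share 3′ ends and with DESeq2 on the genes kept by filterByExpr were chosen after the data were seen, and the others were planned. The fit blocks on treatment, with state alone among the alternatives, and the labels number no replicates to block on. Of 836 list medians under alternatives, 821 kept direction and side, 5 became stronger, 7 weaker and 3 reversed. These cover only the lists and classes chosen for the text, so they do not measure the stability of all lists. Of 2334 values of named genes, 2268 kept their call, 65 lost it, 1 gained it and none reversed; 107 of 138 gene and class pairs held under every alternative. Of 455 shares 378 stayed within their intervals, of 85 gene counts 60 stayed within 1.5-fold, and of 30 hypoxia values per cell 21 stayed within their intervals. For those that follow, the cause was not tested. By the DESeq2 Wald test on genes with at least 1 count, 2856 genes passed in cancer cells, 2105 in CD8 T cells, 284 in conventional CD4 T cells, 300 in regulatory T cells and 797 in macrophages. On the genes kept by filterByExpr, as in edgeR, the DESeq2 counts in the same order were 2894, 2120, 274, 312 and 829. Thinned to 1000 UMIs per cell the counts were 1852 in cancer, 631 in conventional CD4 T, 423 in regulatory T cells and 726 in macrophages. Without the filter on low counts they were 510 in regulatory T cells and 3580 in macrophages. Leaving out each treated library in turn gave 951 to 6681 in cancer, 2011 to 3045 in CD8 T, 52 to 1783 in conventional CD4 T and 757 to 1744 in regulatory T cells, where the lone library of a state is assumed to vary like the other state.

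Shares follow in the order isotype, responding anti-PD-1, responding combination, resistant anti-PD-1 and resistant combination. At 2000 UMIs or more, neutrophils were 0.466%, 1.59%, 10.8%, 1.69% and 6.18%, NK cells 35.2%, 26.1%, 12.3%, 10.9% and 11.9%, and regulatory T cells, the responding combination aside, 12.1%, 6.67%, 23.9% and 16.1%. At 500 UMIs or more, neutrophils were 13.0%, 20.9%, 42.5%, 35.6% and 38.1% and NK cells, the responding combination aside, 27.7%, 18.5%, 6.89% and 7.08%. Neutrophils were 37.0% in the responding combination with doublets kept and 28.9% in the resistant combination at 5% mitochondrial UMIs or less. The reversed medians were macrophage proliferation under anti-PD-1 (-0.39, thinned) and MHC class II in NK cells (0.513 under anti-PD-1 with free RNA subtracted, -0.087 under the combination, thinned). The median hypoxia share per cancer cell in isotype was 0.30% at 1000 UMIs, 0.24% at 5000 and 0.239% without thinning, and in the responding combination 0.197% without thinning. The top decile without thinning was 0.635% and 0.533% in response (0.54% for the combination at 5000 UMIs) and 1.028% and 0.99% in resistance. Depth limits neutrophils most, with a median of 1185 UMIs per cell in isotype.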

Other observations

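The tests of hypoxia-rich cancer cells in this part were written before their results were seen, and no test here was chosen after.

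Neutrophils and NK cells were left out of the edgeR test, which was set for 5 other classes, and their list medians are given as values. In neutrophils the hypoxia list stood at 1.38 under anti-PD-1 and 1.34 under the combination, at percentile 100.0 among 10000 random lists matched on mean expression, the interferon-γ response list at -2.99 and -2.97 and the MHC class I list at -1.54 and -1.71, all at percentile 0.0. Free RNA made up 4.1% and 3.46% of neutrophil UMIs in resistance, 11.16% and 8.63% in response and 10.29% in isotype, and transcripts of cancer cells stood at -1.187 and -0.769 in neutrophils. With free RNA subtracted the hypoxia, interferon-γ response and MHC class I medians of neutrophils kept their direction, at percentiles 100.0, 0.0 and 0.0. In NK cells the glycolysis list stood at 0.96 and 0.80 at percentile 100.0, and the hypoxia list at 0.10 and 0.20 at percentiles 96.1 and 97.4. Mesenchymal genes were lower in NK cells too, at -1.466 and -1.561 and percentile 0.0. Free RNA made up 1.58% and 1.3% of NK cell UMIs in resistance, 4.27% and 3.79% in response and 3.89% in isotype.

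Whether hypoxia and low antigen presentation met in the same cancer cells was tested within each library, by comparing the top 25% of cells by hypoxia transcripts with the bottom 25%, against 1000 shuffles of the cells. MHC class I transcripts were lower in the hypoxia-rich cells, beyond the shuffled range, in 5 of 5 libraries. The differences were -0.247, -0.138, -0.101, -0.049 and -0.048 percentage points of UMIs in isotype, responding anti-PD-1, responding combination, resistant anti-PD-1 and resistant combination. In the same order the top 25% held 0.444%, 0.62%, 0.819%, 0.366% and 0.323%, against 0.691%, 0.759%, 0.92%, 0.415% and 0.371% in the bottom 25%. Even the hypoxia-poor cells of the resistant libraries (0.415% and 0.371%) thus held less than the hypoxia-rich cells of the responding libraries (0.62% and 0.819%). The difference within libraries therefore did not account for the difference between states. Interferon-γ response transcripts were lower in 3 of 5 libraries (-0.159, -0.03 and -0.029 in isotype and the resistant libraries), and the differences of -0.018 and 0.081 in the responding libraries did not meet the prediction made for every library. The difference of 0.081 in the responding combination lay above the shuffled range (upper limit 0.076), in the opposite direction.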
